A study of Saccharomyces cerevisiae with 23 samples.

How the data were processed

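RNA from Saccharomyces cerevisiae was analysed by multiplexed primer extension sequencing in 23 libraries, from wild type (the labels' sets WTa and WTb), a mud1 mutant and a nam8 deletion, in log phase and at 48 h in minimal medium with 2% glucose. Per the labels, RNA was extracted with hot acid phenol. The deposited tables give, per intron and library, mature and premature counts, which are whole-number counts with no normalization per the file headers and the values. The authors' processing notes name FastQC, fastp 0.20.0, STAR 2.7.2b and genome build R64, with no role given for each. How reads were assigned to mature or premature products or to gene copies, and whether molecular identifiers were used, is not given in the sources used here, so p-values and intervals cover counting error and the spread between these libraries only. The labels call the mutant mud1D, while the rows of its table carry another suffix, so whether MUD1 was deleted or otherwise mutated was judged only by its counts.

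Library totals of premature plus mature counts ran from 3343811 to 12068685. The 10 largest targets took between 25.1% and 30.5% of each library. The lowest chi-square per degree of freedom between replicates of a group was 21.5, so no library was a copy of another in its group. Libraries of different groups were not compared in this way. Of 284 introns in any table, 265 were listed in all 23 libraries and had a mean of at least 20 counts. A further 9 were absent from every WTa library but listed in the other 18. The lowest mature count in a listed row was 1 and the lowest premature count 0. All 284 had a symbol in the R64 annotation, and 241 matched an annotated intron, which gave coordinates and the 5' splice site. Libraries were grouped by strain set, genotype and condition from the labels. The strain names in the labels differ between libraries of the same set and recur across genotypes, so they were not used for grouping.

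Splicing was tested with edgeR 4.0.16 in R 4.3.3. Premature and mature counts entered as 2 columns per library, with a term per library and a term per group for the premature column, in 1 quasi-likelihood fit of the 23 libraries. The tested value is the change in log2 of premature over mature. Pooled wild type is the mean of the changes in both sets. All tests were two-sided, and adjusted p-values follow Benjamini-Hochberg over the introns of a comparison, with a threshold of 0.05. Abundance was tested the same way on the sum of both counts with TMM scaling and filterByExpr, and is relative to the other primed targets. Lists of genes were tested with camera in limma 3.58.1 at a preset correlation of 0.01, on log2 odds with a pseudocount of 0.5 for splicing and on voom values for abundance, adjusted over all lists and comparisons, and repeated with an estimated correlation. The lists were ribosomal protein genes and all others, meiosis, the Mer1 and Nam8 meiotic regulon, mitochondrial respiration and ribosome, vesicle transport, cytoskeleton, ubiquitin and proteasome, RNA processing and export, snoRNA hosts, genes that regulate their own splicing, signalling and cell cycle, translation factors, nonconsensus 5' splice sites and mating cell type. The ribosomal protein list and all others are complements, so their camera calls mirror each other and are not separate results. A nonconsensus site is an annotated intron whose first 6 bases are not GTATGT. The median premature share per library was compared by exact permutation of libraries, within wild-type set for the wild-type comparison, and adjusted over 21 tests. CPM values, counts scaled to the library total, used a pseudocount of 0.1. Sharing of wild-type libraries by both mutants was simulated 100 times. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the rest.

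The groups, tests, lists, alternatives and the rule for naming introns were chosen before the data were examined, except those named here as added. The rule named, per comparison, the 8 introns (6 targets for abundance) with the largest increase and the 8 with the largest decrease that passed and whose groups of libraries did not overlap (no such condition for the differences between genotypes), the 2 smallest p-values of each list, and a fixed set of genes known from splicing studies. Not every intron that this rule names is reported here. Other choices set beforehand were DESeq2 1.42.0, limma on log2 odds with a pseudocount of 0.5 or 5, centring each library on its median intron, a mean count minimum of 100 or none, the replicate number as a block, the strain name as a term, WTa or WTb alone as wild type, only the groups compared, and leaving out each library. For abundance they were RLE factors, DESeq2, library totals, no filter, spliced counts only and the block, and for the library share a pooled share. Centred libraries were tested with limma on log2 odds with a pseudocount of 0.5. Counts with centred libraries therefore differ from the main edgeR counts in the test as well as in the centring. Thinning every library to the lowest total, the direct comparison of nam8D with mud1D, a fit of the 18 libraries outside WTa, and WTa or WTb alone for abundance were added after the data were seen, as were the tests of the difference between the wild-type sets, of a shared preparation batch and of 5' splice sites. Replicate numbers did not pair the libraries, since same-numbered libraries of a strain set in both conditions had correlated deviations from their group means above 0.1 in 3 of 11 pairs (median 0.03, lowest -0.22). In simulated data of 265 introns, 30 were changed at each of the log2 sizes 0.5, 1 and 2, and 175 were left unchanged. The splicing test recovered 30 of 30 at each size with 6 false calls among the 175. The abundance test recovered 30 of 30 at each size with 4 false calls among 175. Introns not listed in every library were left out of the main tests because a missing value was not taken as 0. The expression of the NAM8 gene was not analysed here.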

Results

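Splicing of yeast introns was compared between wild type and strains with a mutated MUD1 or NAM8 gene, in log phase and after 48 h of culture in minimal medium with 2% glucose. MUD1 and NAM8 both encode proteins of the U1 small nuclear ribonucleoprotein, the particle that first binds the 5' splice site. The mutants are called mud1D and nam8D here. Multiplexed primer extension sequencing starts reverse transcription from primers placed beside chosen introns, so nearly every read tells whether the RNA still held that intron. The 23 libraries formed 8 groups of 3 libraries each, except wild-type set WTa in log phase with 2. The other wild-type set is called WTb, and with both sets pooled wild type had 5 libraries in log phase and 6 at 48 h. Each library held between 3343811 and 12068685 counts over 284 introns, of which 265 were listed in all 23 libraries and were tested. The premature share of an intron is the percentage of its counts that were unspliced. The labels do not say that replicates were separate cultures, so each p-value measures the spread between these samples, which may be technical.

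The targeted genes were examined first. MUD1 encodes an RNA-binding protein of the U1 particle and holds an intron of its own, on chromosome II from 479346 to 479434 in build R64. In the mud1D libraries this intron was listed only in log-phase replicate 1, with 1 mature and 0 premature counts. The 2 WTa log-phase libraries had 3172 and 2395 mature counts, and the 3 WTb log-phase libraries had 1391, 1498 and 1328. At 48 h the WTa libraries had 4894, 5425 and 5543 mature counts and the WTb libraries 2767, 3399 and 2474. The nam8D libraries had 1358, 1447 and 1472 mature counts in log phase and 2849, 2670 and 2180 at 48 h. Premature counts of MUD1 ran from 63 to 289 per library outside mud1D. NAM8 was not among the introns listed, so its loss was not checked here.

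In wild type, the ratio of unspliced to spliced RNA rose from log phase to 48 h mainly in ribosomal protein genes, though the list call was lost with an estimated correlation. RPL22B and RPL18B, each the B copy of a duplicated ribosomal protein gene, and DBP2, which encodes an RNA helicase and has an unusually long intron, rose most. The opposite was seen for GCR1, which encodes an activator of glycolytic genes, and for the meiotic recombination genes DMC1 and PCH2. The ratio was also lower at 48 h for QCR10 and QCR9 of the respiratory chain. HAC1, whose intron is removed outside the spliceosome by the stress sensor Ire1 and tRNA ligase, also fell.

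Of the 265 introns, 137 had a higher and 76 a lower ratio of premature to mature counts in wild type at 48 h than in log phase (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The median log2 change was 0.29. With each library centred on its median intron, which removes a shift shared by all introns, the split was 113 higher and 103 lower in limma. Here and below, counts with centred libraries come from limma, so they differ from the edgeR counts in the test too. RPL22B, on chromosome VI from 64600 to 64920, went from a premature share of 8.10% ± 2.66 (SD, n = 5) to 56.0% ± 6.07 (SD, n = 6), a log2 change of the ratio of 3.83 ± 0.12 (SE, adjusted p = 9.9e-25). RPL18B, on chromosome XIV from 64019 to 64450, went from 47.1% ± 3.44 (SD, n = 5) to 92.1% ± 3.32 (SD, n = 6). DBP2, on chromosome XIV from 414912 to 415913, went from 7.71% ± 0.602 (SD, n = 5) to 40.2% ± 5.31 (SD, n = 6), a log2 change of 2.99 ± 0.13 (adjusted p = 2.7e-20). RPS9A (2.76), SUN4 of the cell wall, RPL21B (2.38), IMD4 of guanine nucleotide synthesis (2.12) and RPL14A (1.97) had the next largest log2 increases. GCR1, on chromosome XVI from 412262 to 413012, fell from 60.0% ± 2.83 (SD, n = 5) to 19.5% ± 3.65 (SD, n = 6), a log2 change of -2.67 ± 0.12 (adjusted p = 2.2e-19). DMC1, on chromosome V from 548553 to 548644, fell from 52.3% ± 6.88 (SD, n = 5) to 12.2% ± 2.99 (SD, n = 6). PCH2 (-2.59), MPT5, which encodes an mRNA-binding repressor (-2.34), the ubiquitin-conjugating enzyme gene UBC5 (-1.91) and the meiotic genes REC114 (-1.83) and MND1 (-1.77) also fell. QCR10 changed by -1.28 ± 0.09 (adjusted p = 3.2e-15) and QCR9 by -0.96 on the log2 scale. HAC1 fell by 3.61 on the log2 scale, but only from a share of 99.9% ± 0.0533 (SD, n = 5) to 99.2% ± 0.0884 (SD, n = 6). REC107, a meiotic gene whose splicing in meiosis needs Nam8, did not pass (0.24 ± 0.15, adjusted p = 0.15).

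Ribosomal protein introns moved apart from the others in wild type. Of the 103 ribosomal protein introns 95 rose and 1 fell with a median log2 change of 1.07, while 42 rose and 75 fell among the 162 introns of other genes, with a median of -0.19. The counts adjusted over the list alone were identical for these and for every list in this comparison. The camera test placed the ribosomal protein introns above the rest (adjusted p = 5.8e-21 at the preset correlation, adjusted p = 0.184 with an estimated correlation) and the others below it (adjusted p = 0.150 with an estimated correlation). Lower ratios were also called by camera for meiosis, with 5 of 7 introns lower and 0 higher (adjusted p = 0.0308, adjusted p = 0.367 with an estimated correlation), and for mitochondrial respiration and ribosome, with 5 of 6 lower and 0 higher (adjusted p = 0.00996, adjusted p = 0.263 with an estimated correlation). The wild-type sets differed in size here, as the premature CPM (counts scaled to the library total) summed over the meiosis list was 130 and 127 in the WTa log-phase libraries and between 64.3 and 86.1 in those of WTb. Outside the tests, MEI4 had 255 and 195 premature counts in WTa log phase, against 9 and 16 where WTb listed it. SAE3 had 101 and 82, against 7, 11 and 17. SPO22 did not stand apart, with 6 in WTa replicate 3 against 5 and 4. Whether this excess bears on the fall of the meiosis list was not tested. MND1 fell from 69.3% to 30.1% in WTa and from 43.8% to 26.4% in WTb, and DMC1 from 57.0% to 9.78% and from 49.2% to 14.6%. Genes known to regulate their own splicing had 8 introns higher and 1 lower of 9 (adjusted p = 0.0405, adjusted p = 0.407 with an estimated correlation). Camera made no call for the remaining lists with at least 3 introns. In those, 8 rose and 1 fell of 11 introns in snoRNA host genes, 3 rose and 7 fell of 16 in vesicle transport, and 5 rose and 4 fell of 11 in cytoskeleton genes. Ubiquitin and proteasome genes had 3 higher and 1 lower of 8, RNA processing and export genes 7 higher and 5 lower of 15, and signalling and cell cycle genes 3 higher and 5 lower of 9. Translation factor genes had 2 higher and 0 lower of 4. The introns with a nonconsensus 5' splice site had 27 higher and 16 lower of 48. The list of the Mer1 and Nam8 meiotic regulon had 0 higher and 1 lower (PCH2) of 2 measured. Among the mating cell type introns, the second of HMRA1 fell (-0.98) and the first rose (0.25, adjusted p = 0.015). The rise of the first HMRA1 intron no longer passed without WTa log-phase replicate 2 (0.18) and turned to -0.0178 with WTb alone as wild type. Its reads cannot be separated here from those of the near-identical active mating type locus.

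The premature share of the median ribosomal protein intron rose from 0.546% ± 0.0125 (SD, n = 5) to 1.11% ± 0.131 (SD, n = 6) in wild type. The two-sided exact permutation p, with libraries exchanged within each wild-type set, was 0.005, the smallest possible, and 0.0278 after adjustment over 21 such tests. For the median intron of other genes the share fell from 10.6% ± 0.856 (SD, n = 5) to 8.43% ± 1.66 (SD, n = 6), with the same permutation p of 0.005. The share of the median intron fell from 9.78% to 7.03% in WTa and from 11.2% to 9.83% in WTb. With counts pooled over introns the change no longer passed, as the share went from 11.7% ± 0.172 (SD, n = 2) to 10.6% ± 0.198 (SD, n = 3) in WTa and from 14.8% ± 0.0709 (SD, n = 3) to 14.7% ± 0.723 (SD, n = 3) in WTb.

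**Figure D1:**
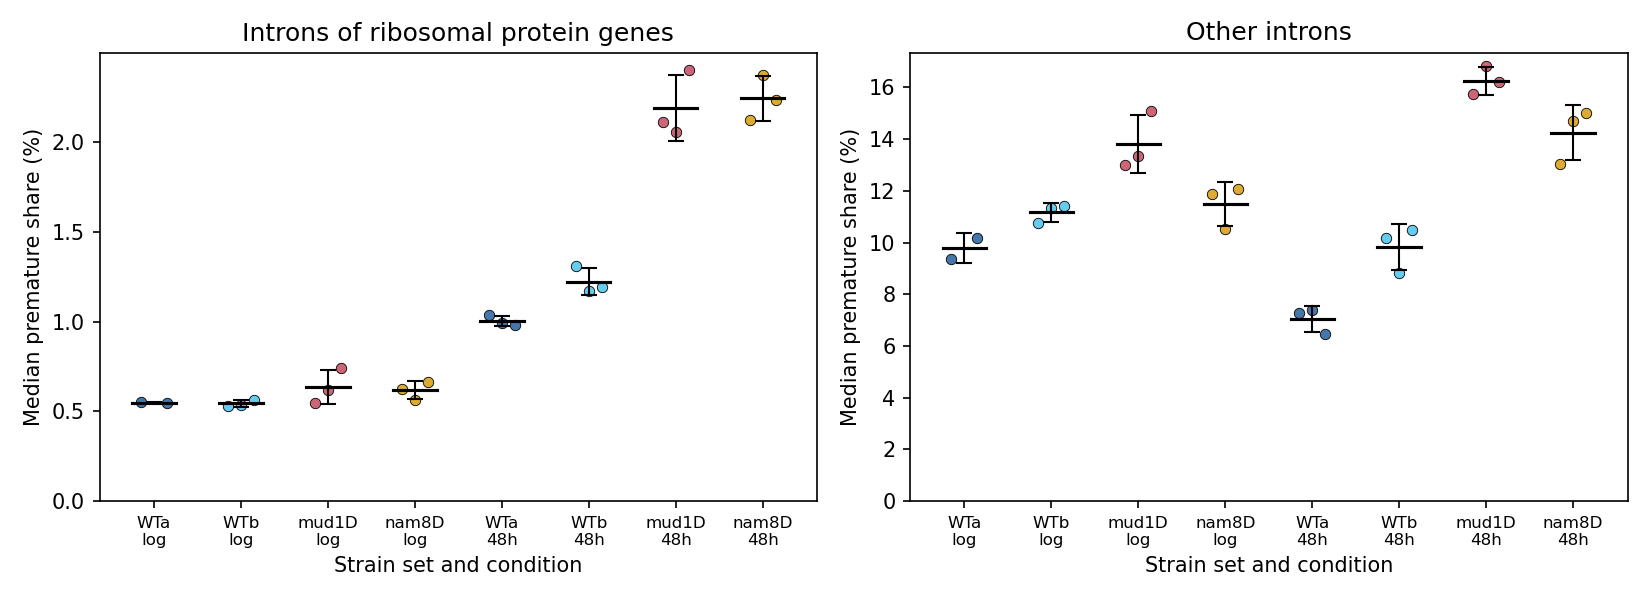
Median premature share per library, in percent (y axis), over ribosomal protein introns and over the introns of other genes, by strain set and condition (x axis), with points for libraries, horizontal lines for group means and error bars for SD. At 48 h the ribosomal protein introns reached 1.11% in pooled wild type, 2.19% in mud1D and 2.24% in nam8D.

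In both mutants most introns that changed by 48 h rose. RPL18B, RPL22B, DBP2 and IMD4 were among the largest increases, as in wild type, together with the 14-3-3 protein gene BMH2, and ECM33, which encodes a cell surface protein, stood out in nam8D. GCR1, HAC1 and the respiratory gene QCR10 still fell. SIM1 of the cell wall and COI1, which encodes a mitochondrial inner membrane protein, fell in both mutants.

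In mud1D 172 introns rose and 41 fell at 48 h against log phase, with a median log2 change of 1.08, and in nam8D 188 rose and 26 fell, with a median of 1.10. After centring each library on its median intron the splits were 133 higher and 97 lower in mud1D and 101 higher and 106 lower in nam8D. DBP2 reached a premature share of 84.4% ± 3.52 (SD, n = 3) in mud1D from 5.94% ± 0.159 (SD, n = 3), a log2 change of 6.43 ± 0.18 (adjusted p = 1.5e-25). In nam8D it reached 84.2% ± 0.363 (SD, n = 3) from 11.5% ± 0.970 (SD, n = 3), a log2 change of 5.36 ± 0.18 (adjusted p = 6.6e-24). RPL22B reached 74.4% ± 1.28 (SD, n = 3) in mud1D and 75.4% ± 1.11 (SD, n = 3) in nam8D, with log2 changes of 5.29 and 5.43. BMH2 rose from 2.52% ± 0.156 (SD, n = 3) to 35.4% ± 1.47 (SD, n = 3) in mud1D and from 3.19% ± 0.0381 (SD, n = 3) to 37.3% ± 3.68 (SD, n = 3) in nam8D. IMD4 rose by 4.55 in mud1D and 4.23 in nam8D on the log2 scale. RPL18B rose by 6.20 in mud1D and 5.33 in nam8D, where how reads of duplicated genes were told apart is not given in the sources used here. ECM33 rose in nam8D from 23.9% ± 3.32 (SD, n = 3) to 85.1% ± 3.67 (SD, n = 3), a log2 change of 4.21 ± 0.18. GCR1 fell by 1.40 in mud1D and by 1.70 in nam8D on the log2 scale, and HAC1 fell by 3.32 and 4.03. SIM1 fell by 1.96 in mud1D and 1.10 in nam8D, and COI1 fell by 1.70 and 1.57. REC107 rose in mud1D (1.75 ± 0.38, adjusted p = 7.7e-05) and did not pass in nam8D (0.42 ± 0.42, adjusted p = 0.36).

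Of the 103 ribosomal protein introns 98 rose and 1 fell in mud1D (99 and 1 adjusted over the list alone), and 100 rose and 2 fell in nam8D (100 and 2 adjusted over the list alone). Camera called them higher than the rest in mud1D (adjusted p = 3.9e-17, adjusted p = 0.263 with an estimated correlation) and in nam8D (adjusted p = 4.8e-13, adjusted p = 0.367 with an estimated correlation). Mitochondrial respiration and ribosome genes went the other way in mud1D, with 0 of 6 higher and 5 lower (0 and 5 adjusted over the list alone, camera adjusted p = 2.0e-04, adjusted p = 0.150 with an estimated correlation). In nam8D 1 was higher and 5 lower (camera adjusted p = 4.6e-05, adjusted p = 0.150 with an estimated correlation). The meiosis list had 0 higher and 1 lower of 7 in nam8D (camera adjusted p = 0.0133, adjusted p = 0.263 with an estimated correlation), and 0 higher and 6 lower with centred libraries. Among the 162 introns of other genes 74 rose and 40 fell in mud1D (74 and 39 adjusted over the list alone), and 88 rose and 24 fell in nam8D (87 and 23 adjusted over the list alone). Camera called these others lower than the rest in both mutants although their medians were 0.27 and 0.48 (adjusted p = 0.184 and 0.263 with an estimated correlation). The direction turned with centring, to 40 higher and 92 lower in mud1D and 28 higher and 99 lower in nam8D. The median premature share of ribosomal protein introns went from 0.637% ± 0.0958 (SD, n = 3) to 2.19% ± 0.186 (SD, n = 3) in mud1D and from 0.618% ± 0.0503 (SD, n = 3) to 2.24% ± 0.125 (SD, n = 3) in nam8D. For other introns it went from 13.8% ± 1.11 (SD, n = 3) to 16.2% ± 0.542 (SD, n = 3) in mud1D and from 11.5% ± 0.849 (SD, n = 3) to 14.3% ± 1.07 (SD, n = 3) in nam8D. Groups of 3 against 3 cannot give an exact permutation p under 0.1, and both changes over all introns had that value.

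**Figure D2:**
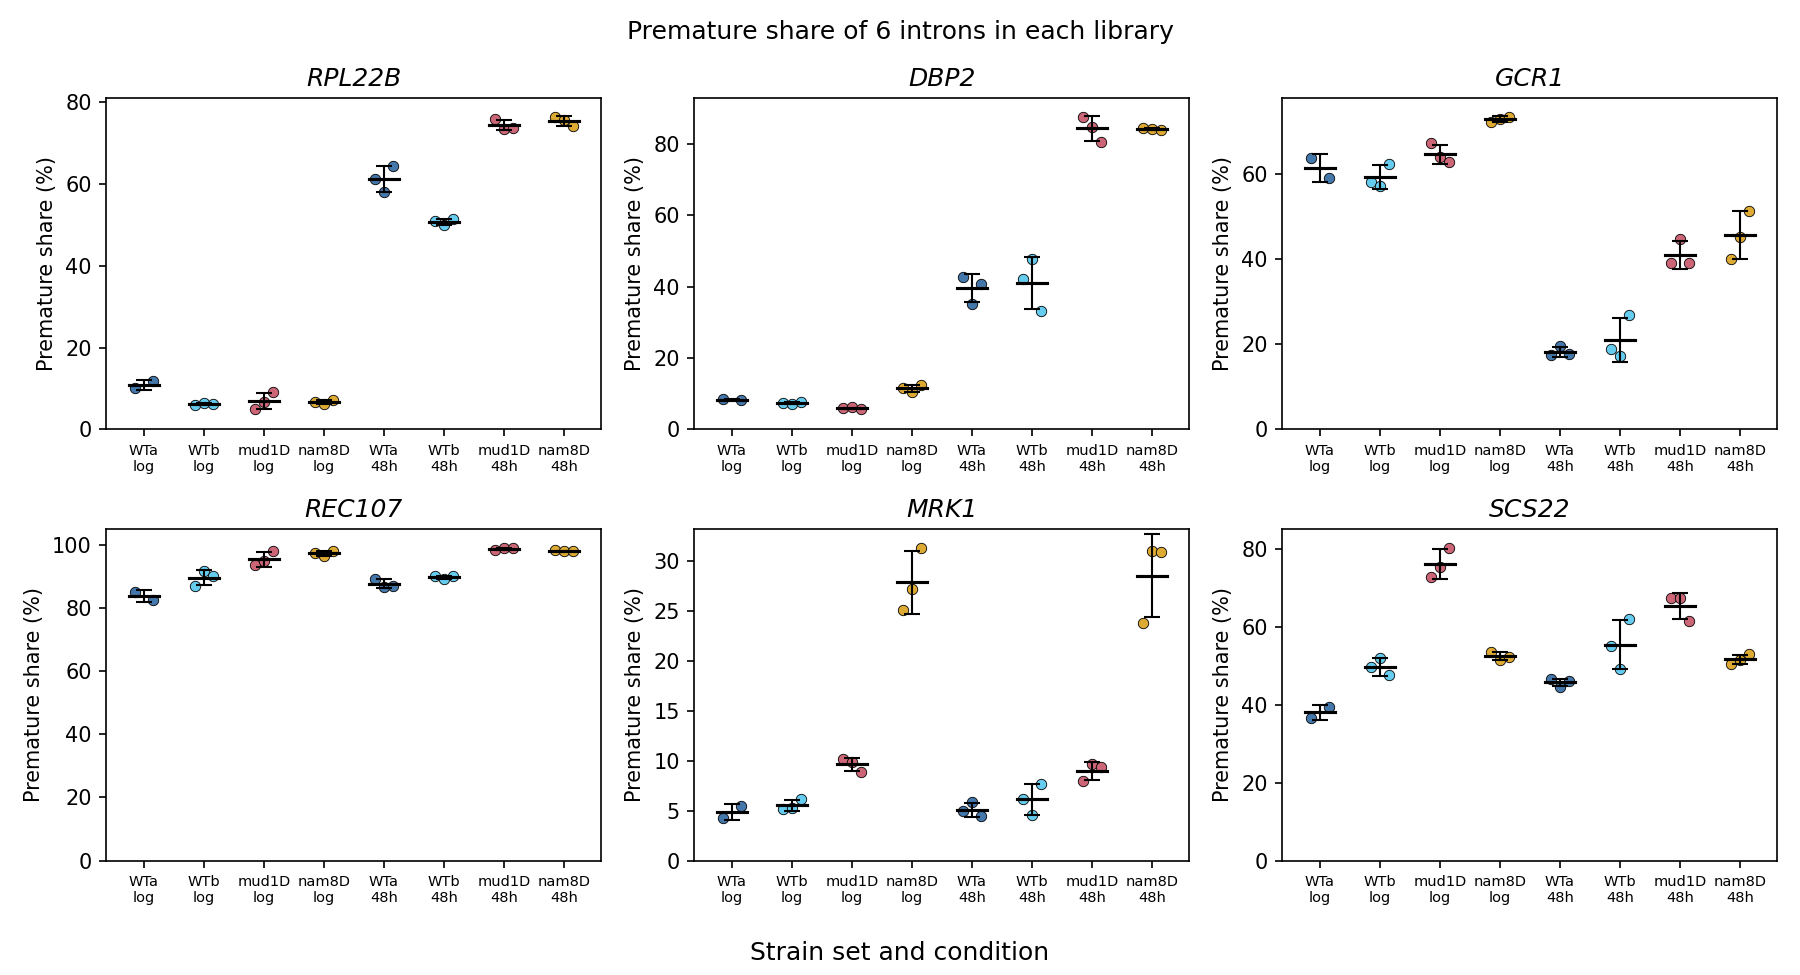
Premature share in percent (y axis) of the introns of RPL22B, DBP2, GCR1, REC107, MRK1 and SCS22 in each library by strain set and condition (x axis), with points for libraries, horizontal lines for group means and error bars for SD. MRK1 is higher in nam8D in both conditions (27.9% and 28.6%), SCS22 is higher in mud1D (76.1% and 65.4%), and DBP2 at 48 h reaches 84.4% in mud1D and 84.2% in nam8D.

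In log phase some of the introns that rose most were shared by the mutants and others were not. In mud1D the ratio of unspliced to spliced RNA was higher for SCS22, which tethers the endoplasmic reticulum to the plasma membrane, and PCC1 of the KEOPS tRNA modification complex. It was also higher for several of the ubiquitin and vesicle transport genes. In nam8D the glycogen synthase kinase homologue MRK1 and the mitochondrial gene CQD1 were among the largest. REC107, the meiotic gene, rose in both mutants, and so did LSM7 of the U6 snRNP and CMC4 of the mitochondrial intermembrane space.

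In mud1D 127 introns were higher and 21 lower than in wild type in log phase, with a median log2 change of 0.31. Centred libraries gave 57 higher and 94 lower. SCS22, on chromosome II from 47059 to 47146, had a premature share of 76.1% ± 3.78 (SD, n = 3) against 45.1% ± 6.70 (SD, n = 5) in wild type, a log2 change of 2.04 ± 0.14 (adjusted p = 6.3e-14). PCC1, on chromosome XI from 625902 to 625976, had 19.8% ± 3.40 (SD, n = 3) against 6.85% ± 0.674 (SD, n = 5), a log2 change of 1.72 ± 0.19 (adjusted p = 2.2e-09). REC107, on chromosome X from 469184 to 469263, had 95.3% ± 2.31 (SD, n = 3) against 87.2% ± 3.66 (SD, n = 5), a log2 change of 1.62 ± 0.26 (adjusted p = 2.6e-06). CMC4 (1.62), the second intron of YOS1 (1.52), GPI15 (1.51), USV1 (1.44) and YOP1 (1.43) followed. UBC8 rose by 1.38 and UBC13 by 1.10 on the log2 scale. Ubiquitin and proteasome genes had 7 higher and 0 lower of 8 (7 and 0 adjusted over the list alone), and vesicle transport genes 10 higher and 0 lower of 16 (11 and 0 adjusted over the list alone). Mitochondrial respiration and ribosome genes had 5 higher and 0 lower of 6 (5 and 0 adjusted over the list alone). With centred libraries the ubiquitin genes had 6 higher and 0 lower, the vesicle transport genes 6 higher and 5 lower, and the mitochondrial genes 2 higher and 0 lower. Camera made no call for these lists (adjusted p = 0.0803, 0.411 and 0.212). Introns outside ribosomal protein genes had 102 higher and 8 lower of 162 (103 and 10 adjusted over the list alone) and were called higher than the rest by camera (adjusted p = 1.6e-07, adjusted p = 0.498 with an estimated correlation). Ribosomal protein introns had 25 higher and 13 lower of 103 (22 and 12 adjusted over the list alone), which became 2 higher and 59 lower with centred libraries. Camera called them lower than the rest, although their median log2 change was 0.08 (adjusted p = 1.6e-07, adjusted p = 0.677 with an estimated correlation). RPL31A fell most (-1.18, adjusted p = 8.2e-06), but against WTb alone it no longer passed (-0.31).

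In nam8D 78 introns were higher and 19 lower than in wild type in log phase, with a median log2 change of 0.17. Centred libraries gave 79 higher and 37 lower. MRK1, on chromosome IV from 314045 to 314336, had a premature share of 27.9% ± 3.15 (SD, n = 3) against 5.27% ± 0.693 (SD, n = 5) in wild type, a log2 change of 2.82 ± 0.20 (adjusted p = 1.7e-13). CQD1, on chromosome XVI from 345445 to 345596, had 33.6% ± 2.10 (SD, n = 3) against 14.3% ± 2.13 (SD, n = 5), a log2 change of 1.59 ± 0.20 (adjusted p = 7.0e-08). REC107 had 97.2% ± 0.765 (SD, n = 3), a log2 change of 2.41 ± 0.28 (adjusted p = 3.4e-08). LSM7 (1.54), ASC1 (1.25), CMC4 (1.24) and SUN4 (1.21) were also higher. The largest decrease, that of the meiotic gene MND1 (-1.59), did not pass against WTb alone (-0.87). Ribosomal protein introns had 28 higher and 6 lower (28 and 6 adjusted over the list alone) and the others 50 higher and 13 lower (52 and 14 adjusted over the list alone). Camera called no list in nam8D in log phase.

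Calls in log phase were fewer with WTb alone as wild type. Against WTb alone 85 introns were higher and 3 lower in mud1D, and 30 were higher and 1 lower in nam8D, of 274 tested. Wild type then had 3 log-phase libraries in place of 5, so a lower power and the choice of set cannot be told apart. Over all introns the median premature share was 4.18% ± 0.121 (SD, n = 5) in wild type and 5.49% ± 0.555 (SD, n = 3) in mud1D (two-sided exact permutation p = 0.0179, adjusted 0.0312). In nam8D it was 4.37% ± 0.235 (SD, n = 3), which did not pass (exact permutation p = 0.179, adjusted 0.188). With counts pooled over introns the nam8D share did pass, at 2.15% ± 0.0998 (SD, n = 3) against 1.60% ± 0.0144 (SD, n = 2) in WTa and 1.87% ± 0.0327 (SD, n = 3) in WTb (exact permutation, adjusted p = 0.0312). For ribosomal protein introns alone nam8D passed against wild type (exact permutation p = 0.0179, adjusted 0.0312) and mud1D did not (exact permutation p = 0.0536, adjusted 0.0865).

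At 48 h unspliced RNA was higher in both mutants for almost all introns. DBP2, BMH2 and the meiotic gene DMC1 were among the introns with the largest differences in each mutant, and REC107 was higher in both. CQD1, ECM33, MRK1 and the second intron of RPL7A were also among the largest in nam8D. SRC1, which encodes an inner nuclear membrane protein through alternative 5' splice sites, and RPL16B stood out in mud1D. RPS9A, SIM1 and RPS14B, which is regulated by its own protein through splicing, were lower in mud1D, and COI1 was lower in nam8D.

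In mud1D 240 introns were higher and 3 lower than in wild type at 48 h, with a median log2 change of 1.11, and in nam8D 234 were higher and 3 lower, with a median of 1.01. Centred libraries gave 117 higher and 60 lower in mud1D and 102 higher and 79 lower in nam8D, a balance that centring largely sets by construction. REC107 changed by 3.14 ± 0.24 in mud1D (adjusted p = 7.9e-14), from 88.6% ± 1.47 (SD, n = 6) in wild type to 98.6% ± 0.377 (SD, n = 3), and by 2.59 in nam8D. DBP2 changed by 3.02 ± 0.15 (adjusted p = 2.6e-18) in mud1D and by 2.99 in nam8D, and BMH2 by 2.55 and 2.66. DMC1, at 12.2% in wild type, stood at 43.4% ± 2.65 (SD, n = 3) in mud1D and 46.6% ± 6.81 (SD, n = 3) in nam8D. SRC1 was higher by 2.60 and RPL16B by 2.44 in mud1D. CQD1 had 54.8% ± 7.21 (SD, n = 3) in nam8D against 7.37% ± 1.48 (SD, n = 6) in wild type, a log2 change of 3.94 ± 0.15 (adjusted p = 1.5e-21). ECM33, on chromosome II from 393181 to 393510, had 85.1% ± 3.67 (SD, n = 3) in nam8D against 30% ± 3.54 (SD, n = 6), a log2 change of 3.76 ± 0.16 (adjusted p = 1.6e-20). The second intron of RPL7A had 4.52% ± 0.321 (SD, n = 3) in nam8D against 0.611% ± 0.262 (SD, n = 6), a log2 change of 3.05, and MRK1 changed by 2.76 ± 0.14 (adjusted p = 2.7e-18). RPS9A fell by 1.75, SIM1 by 1.18 and RPS14B by 0.76 on the log2 scale in mud1D, and COI1 fell by 0.96 in nam8D.

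Ribosomal protein introns and the others both shifted upward at 48 h, and camera called no list. In mud1D 94 ribosomal protein introns were higher and 2 lower (94 and 2 adjusted over the list alone), and 146 others were higher and 1 lower (146 and 1 adjusted over the list alone). In nam8D the counts were 91 and 1 (91 and 1 adjusted over the list alone) and 143 and 2 (143 and 2 adjusted over the list alone). All 15 RNA processing introns, all 9 signalling introns and all 8 ubiquitin introns were higher in mud1D. With centred libraries these lists had 9 higher and 3 lower, 5 higher and 1 lower, and 2 higher and 2 lower. The median premature share over all introns was 8.97% ± 0.222 (SD, n = 3) in mud1D and 8.99% ± 0.798 (SD, n = 3) in nam8D, against 5.04% ± 0.811 (SD, n = 6) in wild type. Each mutant gave the smallest possible two-sided exact permutation p of 0.0119 (adjusted 0.0278). The median log2 change of premature CPM against wild type was 0.92 in mud1D and 0.77 in nam8D, and that of mature counts was -0.16 and -0.14.

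**Figure D3:**
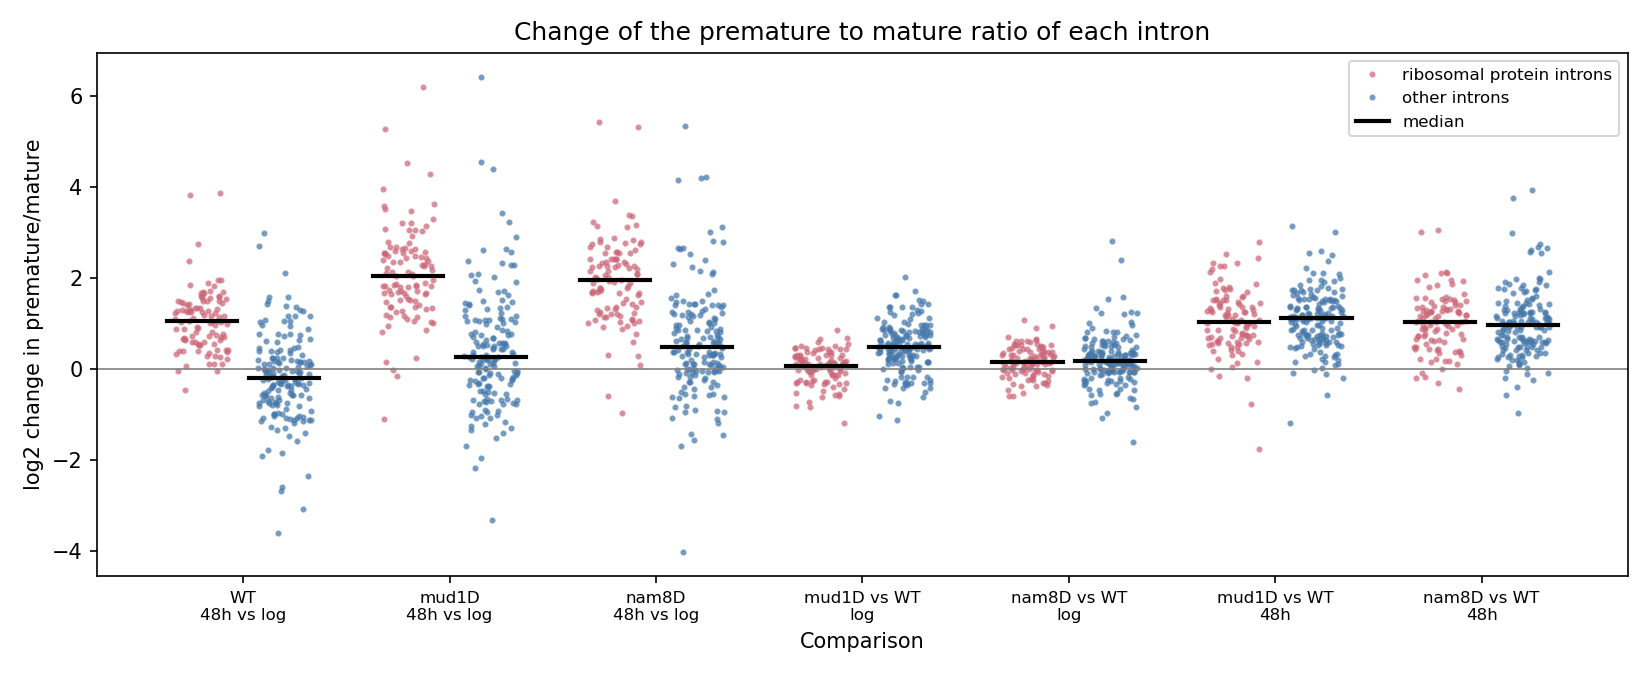
Log2 change of the premature to mature ratio (y axis) of each of 265 introns in 7 comparisons (x axis), with a point per intron, ribosomal protein introns in red, other introns in blue and horizontal lines for medians. In wild type the medians lie apart at 48 h against log phase (1.07 and -0.19), while against wild type at 48 h nearly all introns lie above 0 in both mutants.

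The mutants were compared with the same wild-type libraries, which alone makes their changes correlate. Across introns, which are not independent replicates, the log2 changes of mud1D and nam8D correlated with r = 0.567 in log phase, where simulated shared controls gave 0.389, and with r = 0.786 at 48 h, where simulation gave 0.334. When each mutant was set against different wild-type libraries, r fell to 0.106 and 0.187 in log phase but stayed at 0.577 and 0.585 at 48 h. In log phase 59 introns were higher in both mutants against the shared libraries, and 14 and 37 when the mutants were set against different wild-type sets. Independent calls would share 37.4 in log phase and 212 at 48 h against the shared libraries, values that leave out the effect of sharing. At 48 h the counts were 231 against the shared libraries and 203 and 214 against different sets.

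The change from log phase to 48 h differed from wild type in both mutants, mostly toward a higher ratio of unspliced to spliced RNA. DBP2 and BMH2 rose more in mud1D, and BMH2, ECM33 and the second intron of RPL7A rose more in nam8D. DMC1, whose ratio fell in wild type, did not pass in either mutant on its own, and the difference passed in both. ACT1, the actin gene, rose more in nam8D than in wild type. RPS9A and SIM1 rose less or fell more in mud1D.

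The test of the difference called 173 introns higher and 13 lower in mud1D, with a median log2 difference of 0.72, and 201 higher and 8 lower in nam8D, with a median of 0.81. Centred libraries gave 106 higher and 48 lower in mud1D and 49 higher and 61 lower in nam8D, where centring by construction moves the balance toward equal numbers. DBP2 differed by 3.44 ± 0.22 (adjusted p = 6.7e-15) in mud1D and by 2.37 in nam8D. DMC1 differed by 3.21 ± 0.29 (adjusted p = 3.2e-11) in mud1D and by 3.22 ± 0.29 (adjusted p = 2.6e-11) in nam8D. BMH2 differed by 2.81 in mud1D and 2.57 in nam8D, and RPL16B by 3.27 in mud1D. ECM33 differed by 3.05 ± 0.23 (adjusted p = 5.6e-13), the second intron of RPL7A by 2.42, CQD1 by 2.36 and ACT1 by 2.04 in nam8D. RPS9A (-1.44), SIM1 (-1.42) and SCS22 (-1.15) went the other way in mud1D. Ribosomal protein introns had 89 higher and 4 lower in mud1D (90 and 4 adjusted over the list alone) and were called higher by camera (adjusted p = 4.6e-05, adjusted p = 0.917 with an estimated correlation). In nam8D they had 84 higher and 4 lower (85 and 4 adjusted over the list alone), with no camera call, and centred libraries gave 26 higher and 20 lower. The other introns had 84 higher and 9 lower in mud1D (81 and 7 adjusted over the list alone) and 117 higher and 4 lower in nam8D (117 and 4 adjusted over the list alone). Centred libraries left these others at 44 higher and 42 lower in mud1D and turned them to 23 higher and 41 lower in nam8D. In mud1D camera called the others lower than the rest although their median was 0.50 (adjusted p = 4.6e-05, adjusted p = 0.799 with an estimated correlation). It also called the mitochondrial list, with a median of -0.04 and a mean of 0.01, lower (adjusted p = 0.0308, adjusted p = 0.384 with an estimated correlation), and the ubiquitin list, with a median of 0.18, lower (adjusted p = 0.0227, adjusted p = 0.498 with an estimated correlation).

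The abundance of intron-containing RNAs, spliced and unspliced together, changed at 48 h in every genotype. Most ribosomal protein and snoRNA host RNAs fell relative to the other targets, and most of those of respiration, ubiquitin and RNA processing genes rose, though with an estimated correlation only the ribosomal protein calls in wild type and mud1D held among the camera calls for these lists. QCR10 and COX4 of the respiratory chain and MRA1 rose in wild type and in both mutants. SUN4, IMD4 and TEF4, a translation elongation factor gene, fell in wild type and in both mutants.

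In wild type 139 targets rose and 101 fell (edgeR with TMM scaling), in mud1D 133 rose and 110 fell, and in nam8D 126 rose and 109 fell. With library totals alone as the scale nam8D had 153 higher and 78 lower. The scale was set by the primed targets alone, and the median log2 change in wild type was 0.18 with TMM, -0.07 with RLE factors and 0.43 with library totals. QCR10 rose by 3.90 ± 0.08 in wild type (adjusted p = 1.7e-22), 4.48 in mud1D and 3.93 in nam8D, and MRA1 rose by 4.41 in wild type and 4.80 in mud1D, and passed in nam8D as well. COX4 rose by 3.49, 4.24 and 3.58. The meiotic gene MND1 rose by 2.91 in wild type, 5.59 in mud1D and 5.31 in nam8D, though the difference between genotypes was not tested. SUN4 fell by 3.86 in wild type, 3.90 in mud1D and 3.85 in nam8D, IMD4 fell by 2.61, 2.84 and 3.11, and TEF4 fell by 1.88, 3.48 and 2.98. Ribosomal protein targets had 9 higher and 85 lower of 103 in wild type (9 and 85 adjusted over the list alone), with a median of -0.56 that stayed negative under each scaling (-0.81 and -0.30). Camera called them lower in wild type (adjusted p = 8.0e-32, adjusted p = 0.00385 with an estimated correlation), in mud1D (adjusted p = 8.5e-22, adjusted p = 0.0164 with an estimated correlation) and in nam8D (adjusted p = 8.7e-15, adjusted p = 0.0579 with an estimated correlation). In wild type snoRNA hosts had 1 higher and 9 lower of 11 (camera adjusted p = 0.00191, adjusted p = 0.258 with an estimated correlation). Mitochondrial genes had 6 higher of 6 (adjusted p = 0.0412, adjusted p = 0.258 with an estimated correlation) and vesicle transport genes 13 higher and 1 lower of 16 (adjusted p = 0.0286, adjusted p = 0.430 with an estimated correlation). Ubiquitin and proteasome genes had 8 higher of 8 (adjusted p = 0.0334, adjusted p = 0.258 with an estimated correlation), and RNA processing genes 13 higher and 0 lower of 15 (adjusted p = 0.0256, adjusted p = 0.258 with an estimated correlation). In mud1D and nam8D snoRNA hosts had 10 and 9 lower and 1 higher each, mitochondrial genes 5 higher and 1 lower each, and RNA processing genes 13 higher and 2 lower each. Ubiquitin and proteasome genes had 8 higher in mud1D and 7 in nam8D, with 0 lower. Camera called these lists in both mutants, with adjusted p = 0.258 for each with an estimated correlation. It did not call vesicle transport genes in mud1D (camera adjusted p = 0.0971) or nam8D (0.201). Translation factor genes were called lower in nam8D only (camera adjusted p = 0.0353, adjusted p = 0.258 with an estimated correlation). For each of these lists the counts adjusted over the list alone were identical, and the sign of the list's median held under each scaling.

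The wild-type sets differed from each other. WTb had 80 introns with a higher and 46 with a lower ratio than WTa in log phase, and 136 higher and 15 lower at 48 h, where the median log2 difference was 0.37. Centred libraries gave 58 higher and 55 lower at 48 h. Ribosomal protein introns had 24 higher and 24 lower in log phase and 47 higher and 9 lower at 48 h. YRA1, an mRNA export gene that regulates its own splicing, had a premature share of 27.6% ± 1.47 (SD, n = 2) in WTa and 63.0% ± 3.14 (SD, n = 3) in WTb in log phase.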

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

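The tests of the difference between the wild-type sets, of library size and of a shared preparation batch, and the fit of the introns that WTa lacks, were chosen after the results they measure had been seen.

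DBP2, BMH2 and DMC1 stood out in both mutants because their change from log phase to 48 h differed from that in wild type. The test of this difference between groups called 186 introns in mud1D and 209 in nam8D. In fits of only the compared libraries, with wild type as 1 group, 3 of 100 regroupings gave as many calls for each mutant, the real grouping included. The real values were 129 in mud1D and 140 in nam8D and the highest of the other groupings gave 175 and 156. Those regroupings kept all 3 mutant 48 h libraries together. The regroupings therefore cannot separate a difference in change from a difference at 48 h alone, and chance is not excluded for the difference in change. With WTb alone as wild type the counts were 153 and 150.

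SAR1, which encodes the GTPase that starts vesicle budding, and PSP2, which encodes an RNA-binding protein, lie outside the main comparisons because no WTa library lists them. Against WTb they showed the largest signals among such introns, and both were chosen after their values were seen. SAR1, on chromosome XVI from 138726 to 138864, was higher by 2.55 in nam8D (adjusted p = 7.2e-17) and 0.83 in mud1D at 48 h, and by 1.48 in nam8D in log phase. PSP2 was higher by 2.10 in mud1D and 1.59 in nam8D at 48 h. The other introns of this kind that passed at 48 h in mud1D were those of MAF1 (0.81), MMS2 (0.69), YNL050C (0.82), GOT1 (0.38) and the second of EFM5 (0.92). In nam8D they were those of YDL012C (0.42), MMS2 (0.31), YNL050C (0.51), GOT1 (0.33) and the second of EFM5 (1.21).

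The first pattern weighed is the higher premature share in both mutants at 48 h, seen in DBP2, REC107 and most other introns. Genomic DNA carried over would add premature counts alike to introns of weakly and strongly expressed targets, but the gain in the least abundant quartile of targets was 0.120 of that in the most abundant quartile in nam8D (95% interval 0.0767 to 0.224), which argues against it there. In mud1D the ratio was 0.283 (0.120 to 0.540), so DNA cannot be told apart from RNA there because the interval is wide. A difference between the wild-type sets does not account for the pattern, since the median log2 change against WTb alone exceeded the 0.37 between the sets. It was 0.80 in mud1D (range 0.76 to 0.85 with a library left out) and 0.76 in nam8D (range 0.68 to 0.86 with a library left out). The loss of U1 snRNP proteins may contribute and stays open, as does any other difference of culture or preparation at 48 h between mutants and wild type.

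The splits of these libraries bear on chance only. At 48 h 1 of 84 splits, the real one, gave as many calls for each mutant, which argues against chance if replicates were separate cultures. It called 233 introns in mud1D against a highest other of 127, and 221 in nam8D against 133. That other split set the 3 WTa libraries apart from the rest, and the values within WTb alone were 236 and 221. In log phase 2 of 56 splits gave as many, the real one included. The real count was 64 in mud1D and 23 in nam8D, and the highest other gave more, 67 and 68, so chance is not excluded there. That split joined both WTa libraries and WTb replicate 3, and for nam8D it called several times the real count, which points to a structure of the samples. The split that set the 3 WTb libraries apart gave 4 calls with mud1D and 1 with nam8D, but it joined WTa with the mutant. Groups of 3 could not set the 2 WTa libraries apart alone, so whether the structure follows the sets cannot be told from these splits. Against WTb alone log phase gave 88 and 31.

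The second pattern is the difference between WTa and WTb, in which YRA1 took part. After thinning to the lowest library total there were 110 calls in log phase, against 126, and 138 at 48 h, against 151, so library size does not account for it. A preparation batch shared by WTb and the mutants is a candidate explanation, since the log-phase profile of WTb correlated less with WTa (median 0.978) than with mud1D (0.990) and nam8D (0.991). In addition, 9 introns were absent from every WTa library but listed in all other libraries. In WTb their mature counts ran, for example, from 11205 to 14868 for SAR1 and from 37 to 62 for MAF1. The sets thus also differed in which introns were reported. These introns were not part of the comparison of the sets, and why WTa lacks them was not tested. The labels name no batch. They give strain names that differ within and between the sets and recur across genotypes, and with the strain name as a term 82 calls were made in log phase and 90 at 48 h, so a strain difference stays open and no biological explanation was tested further. At 48 h the 10 splits of the WTa and WTb libraries are too few for a share under 0.05, with 160 calls in the real split and 0 in the highest other.

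The third pattern is the lower premature share at 48 h in wild type of 75 introns outside ribosomal protein genes, such as GCR1, UBC5 and QCR10. A constant background of premature counts under rising mature counts stays open, because CPM values cannot decide it. Premature CPM of the 75 introns rose by a median log2 of 0.98 (0.84 to 1.19), where mature CPM rose by 1.98. These values met the criterion set beforehand against a constant background. That criterion took constant counts to leave CPM unchanged. Wild-type library totals were lower at 48 h (4369685 to 5910393) than in log phase (6874843 to 12068685). A constant number of premature counts would therefore also rise as CPM. Premature CPM rose in 245 of all 265 introns, with a median log2 of 0.92. Premature CPM was higher in 66 of the 75 and mature CPM in 74. A change in target abundance fits, with a Spearman rho of -0.552 (-0.656 to -0.421) over 162 introns between the change in abundance and that in the ratio, though both measures share the mature counts. Induction of these genes with faster or fuller splicing may be the cause and was not tested.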

How the results depend on the processing

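Thinned counts and the direct comparison of nam8D with mud1D were chosen after the data were seen. DBP2, RPL22B, BMH2, MRK1, CQD1 and ECM33 kept their calls at 48 h against log phase or against wild type at 48 h under every alternative where they were named. Over the 454 pairs of a named intron and a comparison, 71 lost their call under a setting other than a left-out library and 24 with a library left out. Across settings other than left-out libraries, 4700 values of named introns stayed on the same side of the threshold with the same sign, 119 became weaker, 15 stronger and 17 reversed. Of the values per comparison, 202 were the same, 10 weaker and 2 stronger. For counts of calls, the same means a similar total, whatever the direction of the calls. Centring, tested with limma, therefore counted as the same for mud1D against wild type in log phase, although the balance went from mostly higher to mostly lower.

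Limma with each library centred on its median intron, which removes a shift common to the introns by construction, gave 110 calls for the nam8D difference in change and 151 for nam8D against mud1D in log phase. With the strain name as a term the wild-type sets differed in 82 introns in log phase and 90 at 48 h, and nam8D against mud1D at 48 h gave 35, or 41 with only the groups compared. With WTb alone, log phase gave 88 calls in mud1D and 31 in nam8D. With an estimated correlation 0 list calls held for splicing and 4 for abundance. Those 4 were the ribosomal protein list and its complement in wild type and in mud1D, so they are not 4 separate results. With counts pooled over introns, the nam8D difference in log phase passed at 0.387 percentage points, against 0.188 for the median intron. The wild-type change in other introns no longer passed at -0.636, against -2.05. The cause was not tested, and for centred libraries the effects of limma and of centring are not separated here.

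Limma with centred libraries reversed the first HMRA1 intron in wild type at 48 h (-0.0291), in nam8D at 48 h (-0.79), in mud1D (-0.15) and nam8D (-0.31) against wild type at 48 h, and in the nam8D difference (-0.76). It also reversed the second HMRA1 intron in nam8D at 48 h against wild type (-0.26) and in the nam8D difference (-0.36), REC107 in nam8D at 48 h (-0.69), and PCH2 in mud1D against wild type at 48 h (-0.0750). QCR10 reversed in mud1D (-0.10) and nam8D (-0.30) against wild type at 48 h, and PRE3 in nam8D (-0.00517) and its difference (-0.18). With WTb alone the first HMRA1 intron in wild type (-0.0178), YRA1 (-0.19) and RPL22A (-0.0411) in mud1D in log phase and RPL22A in nam8D in log phase (-0.00525) reversed, and the cause was not tested.

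With a library left out, splicing calls at 48 h against log phase ran from 203 to 215 in wild type, 208 to 216 in mud1D and 206 to 216 in nam8D. Against wild type they ran from 124 to 140 in log phase and 238 to 247 at 48 h in mud1D, and from 75 to 95 and 229 to 241 in nam8D. The differences in change ran from 171 to 191 and 193 to 218, the wild-type sets from 92 to 115 and 121 to 151, and nam8D against mud1D from 67 to 97 and 48 to 75. Abundance ran from 233 to 243, 239 to 248 and 226 to 236. Where WTa log phase was left with 1 library, it was assumed to vary like the other groups.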

Other observations

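The direct comparison of the mutants, and the test of 5' splice sites, were chosen after the data were seen.

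MRK1, CQD1 and, at 48 h, ECM33 had a higher ratio of unspliced to spliced RNA in nam8D than in mud1D. The ratios of SCS22, PCC1 and the ubiquitin genes UBC8 and UBC13 were higher in mud1D in log phase. In log phase 29 introns were higher and 67 lower in nam8D than in mud1D, and centred libraries turned this to 118 higher and 33 lower. MRK1 differed by 1.84 ± 0.21 (adjusted p = 3.1e-08), CQD1 by 1.24 and DBP2 by 1.04. SCS22 differed by -1.53 ± 0.15 (adjusted p = 4.7e-09), PCC1 by -1.37, SNC1 by -1.16, UBC8 by -1.10 and UBC13 by -1.09. Of the 8 ubiquitin and proteasome introns 0 were higher and 6 lower (0 and 7 adjusted over the list alone), and of 16 vesicle transport introns 0 were higher and 7 lower (0 and 9 adjusted over the list alone), and centred libraries gave 0 higher and 3 lower and 1 higher and 5 lower. At 48 h 25 were higher and 47 lower, and 41 passed in all when only these groups were fitted. MRK1 (2.02), CQD1 (1.84), ECM33 (1.64), RPS9A (1.45) and the second intron of RPL7A (1.34) were higher in nam8D, and RPL16B (-1.12) and RPL35B (-1.07) were lower. The 10 splits of these libraries are too few for a share under 0.05, with 97 calls in log phase and 41 at 48 h in the real split and 0 in the highest other.

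A hypothesis was that introns whose 5' splice site departs from the consensus, such as those of CQD1 and REC107, depend more on Nam8, which may bind RNA just downstream of the site. The median log2 change in nam8D against wild type at 48 h was 1.04 for 48 nonconsensus and 1.04 for 175 consensus introns, a difference of -0.00779 (95% interval -0.38 to 0.26, permutation p = 0.880 with 1e+05 permutations). The interval leaves a difference in either direction open.

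The splits of the remaining comparisons bear on chance only. For wild type at 48 h against log phase 1 of 100 splits, the real one, gave as many calls, which argues against chance if replicates were separate cultures. It gave 222 calls in splicing against a highest other of 178, and 244 in abundance against 230. The highest other splits moved 1 library of 48 h to the log-phase group and are close to the real grouping. For the mutants at 48 h against log phase the 10 splits are too few for a share under 0.05. There the real split gave 214 splicing calls in each mutant, and 240 abundance calls in mud1D and 246 in nam8D, and the highest other gave 0.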
